A study of Mus musculus with 39 samples.

How the data were processed

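The series measured RNA and 5-hydroxymethylcytosine (5hmC), an oxidised form of DNA methylation made by TET enzymes, in nasal mucosa of C57BL/6 mice that were wild type (WT), Tet2+/- or Tet2-/-. Per the labels' protocols, allergic rhinitis was induced with ovalbumin (OVA), 75 µg with 2 mg of alum in 200 µl by intraperitoneal injection on days 0, 7 and 14, and then by nasal challenge with 500 µg of OVA in 20 µl on days 16 to 25. Control mice were challenged with PBS instead, and mice were 10 to 12 weeks old, per the labels' protocols. There were 18 RNA libraries, 3 per genotype and treatment, and 16 5hmC libraries, with 2 in each of the WT and Tet2-/- OVA groups and 3 in every other group. An additional 5 input libraries were not used here. The descriptions of the mutant libraries carry mouse codes that RNA and 5hmC libraries share, whereas nothing in the WT labels says that the libraries came from separate animals, so p-values for WT measure the spread between these samples, which may be technical.

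Per the submitters' processing notes, the tools were STAR 2.7, DESeq2 1.26.0, Bowtie2 2.3.5.1 and MACS2 2.2.6, listed without roles. Per the labels' protocols, RNA was extracted with TRIzol, 5hmC-carrying DNA was captured and sequenced on an Illumina HiSeq, and 5hmC reads were mapped with Bowtie2 to build GRCm38 (mm10), keeping unique and non-duplicate matches. The counting tool and gene annotation of the RNA libraries are not given in the sources used here. For each genotype the authors deposited a table with a normalised signal per gene and library, which is the gene's read count divided by a size factor of the library. The same tables hold the authors' deposited log2 fold change, written as control over OVA, and the authors' deposited p-value and adjusted p-value. For each 5hmC library the authors deposited a peak list, in which each peak has a fold enrichment (a ratio over the background of the caller) and −log10 values of p and q. The fold enrichments and −log10 values are the authors' own values per peak. They served to describe or filter peaks within a list and to estimate the background of the caller. Median fold enrichments and counts of filtered peaks were also compared between groups. The lowest −log10 q of each list lay just above 2. Which input library served which peak list is not given in the sources used here. The labels name an input for each mutant genotype and treatment and a single input for WT. Peak lists of a mutant group may therefore share an input that the other treatment did not use. The labels speak of pooling the reads of replicates before peak calling, yet a list per library was deposited, and the lists were treated as libraries.

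Whole reads were recovered from the normalised signal, since low values of a library are whole multiples of the value of a single read. With a tolerance of 1e-06, 100% of the values in each of the 18 libraries came out whole. The recovered totals ranged from 14473976 to 24752788 reads. CPM denotes the reads of a gene scaled to this total of its library. Each table had 52636 genes, of which 52403 were matched to a symbol and coordinates in GENCODE vM21 (GRCm38). Replicate libraries of a group differed by far more than sampling noise, with a chi-square per degree of freedom between 14.0 and 440, so no library was counted as a duplicate. All 18 columns were mapped to a sample by name.

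OVA and control were compared within each genotype's own table with limma 3.58.1 (trend) on log2(normalised count + 1) in R 4.3.3, for genes with a mean of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that log2 scale, which understates the change of low genes. The difference of OVA effects between genotypes was fitted with limma over all 18 libraries with 6 group means. Tet2-/- and Tet2+/- were compared within a treatment with the quasi-likelihood test of edgeR 4.0.16 and TMM on the recovered reads. WT was not tested against the mutants for its level, because the WT libraries carry another naming scheme and probably came from another run. DESeq2 1.42.0 and edgeR on recovered reads were run as alternatives. Where no gene changes, a share of 0.05 of the genes tested is due at an unadjusted p under 0.05. For genes with reads in 1 group only, folds were computed against a floor of 3 counts over the group, with the lower 95% exact counting limit of the ratio beside them, and for groups with 1 to 3 reads the ratio is given with its 95% exact counting interval. Intervals and floors cover counting error only.

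Gene lists were tested with camera in limma with a preset inter-gene correlation of 0.01. Of the 31 lists, with 569 genes, those with at least 5 measured members entered a comparison. The lists covered type 2 cytokines, type 2 epithelial and macrophage response genes, eosinophils, mast cells, B cells, plasma cells, T cells, cytotoxic lymphocytes, neutrophils, macrophages, antigen presentation, interferon-stimulated genes, NF-kB targets, immediate early genes, TET and DNMT genes, olfactory neurons, sustentacular cells, nasal glands, ciliated cells, basal and secretory epithelium, tight junctions, keratinocytes, skeletal muscle, cartilage, erythroid cells, extracellular matrix, endothelium, adipocytes, glia, cell cycle and mitochondrial transcripts. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were alternatives.

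The tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took Tet1, Tet2 and Tet3. It took up to 6 rises and 6 falls with the largest change among genes past the threshold, with a mean of at least 50 and groups that did not overlap. It left out immunoglobulin and T cell receptor variable segments, olfactory and vomeronasal receptors, predicted genes and pseudogenes. Where fewer than 3 passed in a direction, the smallest unadjusted p filled up to 3, said not to pass. In each list with a called member or a test past the threshold it took the 3 members with the smallest p, or 4 for type 2 lists. For 5hmC it took peaks at the genes of the first parts of the rule and at Il4, Il5, Il13, Il33, Tslp and Gata3.

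Before use, each test was run on simulated counts with 50 genes changed at each of 2-, 4-, 8- and 16-fold, all with a mean of at least 50. The main tests made 127 to 190 true calls per simulated comparison, and so many true calls ease the adjusted threshold. The real comparisons called 0 to 13 genes, down to a mean of 10. The shares recovered may therefore overstate what could be found in the real data. For OVA against control in WT, limma recovered 80%, 100%, 100% and 100% of these among 19404 genes. In Tet2+/- it recovered 18%, 76%, 90% and 94% among 19233 genes, and in Tet2-/- 10%, 72%, 94% and 96% among 19309 genes. For Tet2-/- minus WT the shares were 24%, 66%, 90% and 86%, for Tet2+/- minus WT 18%, 78%, 84% and 96%, and for Tet2-/- minus Tet2+/- 28%, 68%, 78% and 90%. For Tet2-/- against Tet2+/-, edgeR recovered 18%, 64%, 96% and 98% in control mice and 8%, 64%, 82% and 100% in OVA mice. False calls of the main tests numbered 4 to 9 per comparison, against 35 to 86 for DESeq2. A list shifted in the simulation was called in every comparison, with 1 false list in Tet2-/- against Tet2+/- under OVA. With an estimated correlation its adjusted p was 0.0197 in WT, 0.0315 in Tet2+/- and 0.0171 in Tet2-/-, and 0.128 in Tet2-/- against Tet2+/- under OVA. Simulated genes were drawn independently, so the count of false lists does not cover lists whose genes move together. Other splits of the real libraries called up to 21 lists.

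Replicate numbers were checked for pairing by the correlation of same-numbered libraries' deviations from their group means. In Tet2-/- the correlations of OVA and control libraries were 0.48, 0.21 and 0.53. Between Tet2-/- and Tet2+/- they were 0.58, 0.20 and 0.46 in control mice and 0.56, 0.16 and 0.46 in OVA mice. These numbers were taken to pair the libraries, on the correlations alone, since the labels give no shared litter or day.

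Peaks were compared as presence or absence with bedtools 2.31.1. Regions were the merged peaks of the libraries compared, with an overlap of at least 1 bp, and a region of a group had a peak in every library of that group and in none of the other. Location was assigned by the peak midpoint, with promoters reaching from 2000 bp upstream to 500 bp downstream of a transcription start. A peak at a gene lay in the gene body or within 2 kb upstream. Peak numbers and shares were compared with exact two-sided permutation tests, and similarity with the Jaccard index of covered bases and exact one-sided permutation tests. On simulated lists, 152 regions were made in 1 group, and 165 were found with 14.6 due by chance. For the relation with RNA, a gene had a peak where at least 2 libraries of a group had one. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

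The depth of the 5hmC libraries is unknown from the lists. The background term of the caller, which may follow depth, was therefore estimated from the fold enrichment and −log10 p of each peak, after the data were seen. In simulation 20 of 20 backgrounds drawn at random were recovered, and the most frequent solution was right for 19; this test replaced an earlier form whose backgrounds had been set near those of the real lists. On the real lists 4 rules for choosing among solutions were tried in turn, and the last was kept as it came out. It gave the same value as the most frequent solution in 13 of 16 libraries. The contrast of interest took opposite signs under these rules. The sign turned through the other libraries, where the most frequent solution was 0, 0.001 and 3.85 and the last rule gave 3.53, 2.28 and 1.91. Depth was left open.

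Alternatives were other pseudocounts (5 and 0.5), no filter or a mean of at least 50, robust variance moderation, other normalisations and tools, the replicate number as a block, stricter peak thresholds (−log10 q of at least 5, fold enrichment of at least 4), 50% reciprocal overlap, the same number of peaks (35918) per library and leaving out each library. Covariates for the level of Bpifb9a and Bpifb9b and of keratinocyte and muscle markers, the fits without the pair of libraries with Xist reads, the authors' deposited calls and the difference of OVA effects on peak numbers, unpaired and paired by replicate number with an exact sign-flip test, were added after seeing the data.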

Results

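RNA was measured by sequencing and 5hmC by capture of 5hmC-carrying DNA in the nasal mucosa of WT, Tet2+/- and Tet2-/- mice with OVA-induced allergic rhinitis and of PBS-challenged controls. The 6 RNA groups had 3 libraries each, with 14473976 to 24752788 recovered reads per library. The 6 5hmC groups had 2 (WT OVA, Tet2-/- OVA) or 3 libraries, with 35918 to 139377 deposited peaks per library and a depth that the lists do not give. The comparisons asked how OVA changed each genotype, whether that change depended on Tet2, how Tet2-/- differed from Tet2+/-, and whether 5hmC moved with treatment and genotype.

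Tet2 encodes a dioxygenase that oxidises 5-methylcytosine to 5hmC and lies on chromosome 3 at 133463679 to 133545139 on the minus strand (GRCm38, ENSMUSG00000040943). Its level was 36.2 ± 5.40 CPM (SD, n = 3) in WT OVA and 35.0 ± 1.92 in WT control libraries. It was 24.7 ± 5.00 in Tet2+/- OVA, 44.0 ± 1.80 in Tet2+/- control, 37.1 ± 10.6 in Tet2-/- OVA and 38.2 ± 9.05 in Tet2-/- control libraries. CPM values fall where a few genes take many reads, and the 10 highest genes took 38.3% to 42.4% of reads in Tet2+/- OVA against 9.89% to 23.6% in Tet2+/- control libraries, so folds are given on the size-factor scale. The gene-level count of Tet2 therefore did not separate the libraries labelled Tet2-/- from the others, and a count over the whole gene cannot show the loss of some exons. With OVA, Tet2 differed by 0.01 ± 0.11 (log2 ± SE) in WT (limma adjusted p = 0.986), −0.29 ± 0.18 in Tet2+/- (0.572) and 0.18 ± 0.19 in Tet2-/- (0.756). Tet3 differed by −0.05 in WT, −0.33 in Tet2+/- and −0.19 in Tet2-/-, and Tet1 by −0.20, 0.09 and −0.40, none past the threshold. The sign of Tet2 and Tet3 in WT, of Tet1 in Tet2+/- and of Tet1 and Tet2 in Tet2-/- turned on leaving out a single library. Between Tet2-/- and Tet2+/-, Tet2 differed by −0.16 in control mice (edgeR adjusted p = 0.9989) and 0.25 in OVA mice. The list of 19 TET, DNMT and related genes did not pass in WT (camera adjusted p = 0.862), Tet2+/- (0.571) or Tet2-/- (0.5003).

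In WT mice, OVA raised Ccl20, a chemokine that draws CCR6-bearing dendritic cells and lymphocytes, and Ighg1, the constant region of IgG1. Ccl20 (chromosome 1, 83116766 to 83119167, plus strand) went from 1.41 ± 0.45 to 33.0 ± 11.6 CPM (SD, n = 3), a log2 change of 4.46 ± 0.29 (limma adjusted p = 0.00245). Ighg1 (chromosome 12, 113325240 to 113330523, minus strand) went from 0.415 ± 0.380 to 64.4 ± 23.8, a log2 change of 7.52 ± 0.69 (adjusted p = 0.0229). These were the 2 genes called of 19621, with 1371 at an unadjusted p under 0.05. The next smallest p-values belonged to the amino acid transporter Slc6a14 (1.74 ± 0.19, adjusted p = 0.0547) and, among lower genes, Col6a1 (−0.46), Eln (−0.53) and Nr1d1 (−0.60), none past the threshold. IgE heavy chain reads (Ighe) numbered 8 in OVA and 0 in control libraries, 2.43-fold higher against a floor of 3 counts over the group (lower 95% exact counting limit 1.56). The mucus-associated Clca1 had 20 and 1 reads, a ratio of 18.2 with a counting interval of 2.92 to 756.

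Of 28 lists tested in WT, 5 rose and 7 fell at the preset correlation. With an estimated correlation no list passed, and the adjusted p of the 12 lists lay between 0.493 and 0.790, so each list call below holds at the preset correlation only. Inflammatory cytokines and NF-kB targets were higher in 22 of 23 members, with a median log2 change of 0.78, 1 member called over all genes and 11 adjusted over the list alone. Il6 (4.11), Il1rn (2.06) and Ccl20 had its smallest p-values, and the list's camera adjusted p was 6.23e-12. Type 2 epithelial and macrophage response genes were higher in 14 of 17 members (median 0.27, camera adjusted p = 0.000129), with 7 rises and 1 fall adjusted over the list alone. Among them were Chil4 (3.64), Arg1 (2.26), Chil3 (1.72) and Spdef (0.91), a regulator of goblet cells. Neutrophil markers rose (9 of 13 higher, median 0.54, 0.00131), with Lcn2 at 3.08 ± 0.36 (gene adjusted p = 0.0619), Chil1 at 2.18 and Csf3r at 0.83, and 5 rises and 1 fall adjusted over the list alone. Interferon-stimulated genes rose (23 of 26 higher, median 0.28, 6.50e-05), with Cxcl10 at 1.93, and so did B cell markers (8 of 9 higher, 0.0449), with Fcer2a at 1.21; neither had a member adjusted over the list alone. Extracellular matrix genes fell (16 of 18 lower, median −0.29, 3.47e-06), with 9 falls and 1 rise adjusted over the list alone, Col5a1 at −0.47 and Timp1 in the other direction at 0.84. Cartilage and bone markers fell (16 of 19 lower, median −0.26, 2.31e-05, 6 adjusted over the list alone), with Acan at −1.82 and Col2a1 at −0.69. Cell cycle genes (17 of 23 lower, 0.000137), glia markers (13 of 13 lower, 0.00131), muscle markers (9 of 12 lower, 0.00852), mitochondrial transcripts (11 of 13 lower, 0.0293) and endothelial markers (9 of 13 lower, 0.0361) also fell, with 0, 0, 0, 0 and 1 members adjusted over the list alone. Type 2 cytokines and their receptors did not pass (0.791), nor did T cell (0.862), antigen presentation (0.862), macrophage (0.862), cytotoxic lymphocyte (0.791), immediate early (0.326), olfactory neuron (0.803), sustentacular (0.104), nasal gland (0.0780), plasma cell (0.0780) or erythroid (0.0514) lists. With a covariate for keratinocyte and muscle markers, whose correlation with treatment was 0.713, the type 2 epithelial (0.0699), neutrophil (0.251), interferon (0.902) and B cell lists (0.460) no longer passed as higher, and NF-kB targets did (0.000223). Of the lists that fell, muscle, glia and mitochondrial transcripts no longer passed, and antigen presentation genes (0.00106), nasal gland proteins and ciliated markers newly tested as lower. The summed keratinocyte genes were at 93.9 to 131 CPM in WT OVA and 67.1 to 106 in WT control libraries, but not every member moved so: Krt6a had 2 reads in OVA and 107 in control libraries, 106 of them in control replicate 2. The call of Ighg1 was lost without WT OVA replicate 1 (0.0642), 2 (0.146) or 3 (0.142), with robust moderation (0.334) and with a covariate for Bpifb9a and Bpifb9b (0.369) or for keratinocyte and muscle markers (0.656). That of Ccl20 was lost with the covariate for Bpifb9a and Bpifb9b (0.0987) or with all 18 libraries in a single fit (0.8999). Over 20 alternatives the adjusted p ranged from 1.41e-12 to 0.656 for Ighg1 and from 1.25e-61 to 0.8999 for Ccl20, at log2 changes of 6.62 to 8.23 and 3.86 to 5.01.

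In Tet2+/- mice, the called genes that rose with OVA were led by Cabs1 and Odam. Cabs1 (chromosome 5, 87979439 to 87981544, plus strand) went from 10.8 ± 2.72 to 435 ± 71.7 CPM (SD, n = 3), a log2 change of 5.90 ± 0.19 (limma adjusted p = 0.000596). Odam, a secreted epithelial protein encoded nearby (87885029 to 87894174), went from 3.31 ± 1.16 to 167 ± 12.1 (6.26 ± 0.29, 0.00303). Bpifb5 (6.88 ± 0.52), a member of the BPI-fold family, the pancreatic-type lipase Pnliprp2 (6.06 ± 0.50), the secretoglobin Scgb2b2 (4.70 ± 0.40) and Derl3 (2.07 ± 0.18), which acts in endoplasmic reticulum quality control, rose with an adjusted p of 0.0257 each. In all, 13 of 19611 genes rose and none fell by limma, 2599 had an unadjusted p under 0.05, and edgeR with TMM called 6, all higher. That only rises were called depended on the test, since 360 of the 838 genes called by DESeq2, 224 of 403 with all 18 libraries in a single fit and 251 of 415 with the replicate number as a block were lower. The remaining called genes fell outside the naming rule by mean level, gene class or size and were named after their values were seen: 2310003L06Rik (4.23), Scgb2b1 (4.18), Sva (5.73), Gm14197, Gm26917, Gm16571 and Olfr1509. The genes with the smallest p among those lower in OVA were Pdxk (−0.89), Zbtb16 (−1.82) and Adh1 (−1.27), with adjusted p from 0.0783 to 0.117. The same libraries differed in a gland signal: Bpifb9a and Bpifb9b took 19.3%, 17.3% and 18.0% of reads in Tet2+/- OVA libraries and 0.554%, 0.0638% and 0.253% in Tet2+/- control libraries.

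Of 28 lists tested in Tet2+/-, 2 rose and 3 fell at the preset correlation. The adjusted p became 0.913 for each of the 5 under an estimated correlation, so none passed there. Plasma cell and immunoglobulin genes rose (11 of 15 higher, median 0.59, camera adjusted p = 0.000271), with 1 member called, 6 adjusted over the list alone, and Derl3, Fkbp11 (1.64) and Xbp1 (0.84) in front, which also serve secretion in other cells. Antigen presentation genes rose (16 of 18 higher, median 0.34, 0.0278), with H2-DMa at 0.61 and none adjusted over the list alone. Ciliated cell markers fell (19 of 20 lower, median −0.40, 0.000123), among them the dynein Dnah9 (−1.54), Cfap43 (−1.06) and Rsph4a (−0.62). Erythroid markers fell in 5 of 5 members (median −0.66, 0.000123), all 5 adjusted over the list alone, with Hbb-bs at −0.71. NF-kB targets fell (15 of 18 lower, median −0.64, 0.0278), with Nlrp3 at −1.35, Sele at −2.09 and Vcam1 at −1.34; neither this list nor the ciliated list had a member adjusted over the list alone. Type 2 epithelial genes were higher in 7 of 19 members (0.512), and nasal gland proteins in 11 of 20 (0.330), with 2 called and Bpifa1 at −2.16. Mast cell markers did not pass (0.571). With the Bpifb9a and Bpifb9b level as a covariate, whose correlation with treatment was 0.962, no gene was called (adjusted p of 1.00 for Cabs1 and Odam), the ciliated and NF-kB lists tested as higher (0.000509 and 0.000168), and the erythroid list did not pass (0.945). Cabs1 stayed called on leaving out each library, whereas Odam was lost without Tet2+/- OVA replicate 2 (0.0537). Without that replicate 1 of the 13 genes was left, 2 without OVA replicate 1 (with 1 gene newly called), 3 without OVA replicate 3, 2 without control replicate 1, 4 without control replicate 2 and 7 without control replicate 3, where 12 genes were called. Bpifb5, Pnliprp2, Scgb2b2 and Derl3 were lost without each OVA library, with an adjusted p up to 0.380, and without control replicate 1, where it reached 0.116. Control replicate 2 ended the calls of Pnliprp2, Scgb2b2 and Derl3 (up to 0.158), and control replicate 3 that of Bpifb5 (0.0543). Over 20 alternatives the adjusted p ranged from 5.19e-166 to 1.00 for Cabs1 and from 2.06e-110 to 1.00 for Odam.

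In Tet2-/- mice, OVA raised Itln1, an intelectin secreted by goblet cells, and Ighg1. Itln1 (chromosome 1, 171518122 to 171535294, minus strand, ENSMUSG00000038209) went from 2.94 ± 1.03 to 356 ± 208 CPM (SD, n = 3), a log2 change of 7.01 ± 0.37 (limma adjusted p = 0.00902). The OVA libraries stood at 585, 180 and 303. Ighg1 changed by 9.04 ± 0.50 (0.00902), with 2411 reads in OVA and 2 in control libraries, a ratio of 1460 with a counting interval of 404 to 12066. The third called gene, Gm9765 (5.90 ± 0.44, 0.0406), is a pseudogene next to Itln1 and was named after its values were seen. It had 174 and 0 reads, 70.3-fold higher against the floor (lower counting limit 56.5), and may share reads with Itln1. Of 19666 genes 1316 had an unadjusted p under 0.05, and edgeR called 0 and DESeq2 102. With the replicate number as a block, which the pairing check favoured, limma called 17 genes. Genes that did not pass included Clca3a2 (2.88, adjusted p = 0.0953), Ugt1a7c (−2.30), Pparg (−1.39) and Gcnt3 (−1.91). Ighe had 27 and 0 reads, 10.9-fold higher against the floor (lower counting limit 8.27), Il5 11 and 3 reads (ratio 4.44, interval 1.17 to 24.8) and Cxcl2 69 and 2 reads (ratio 41.8, interval 11.1 to 352).

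**Figure D1:**
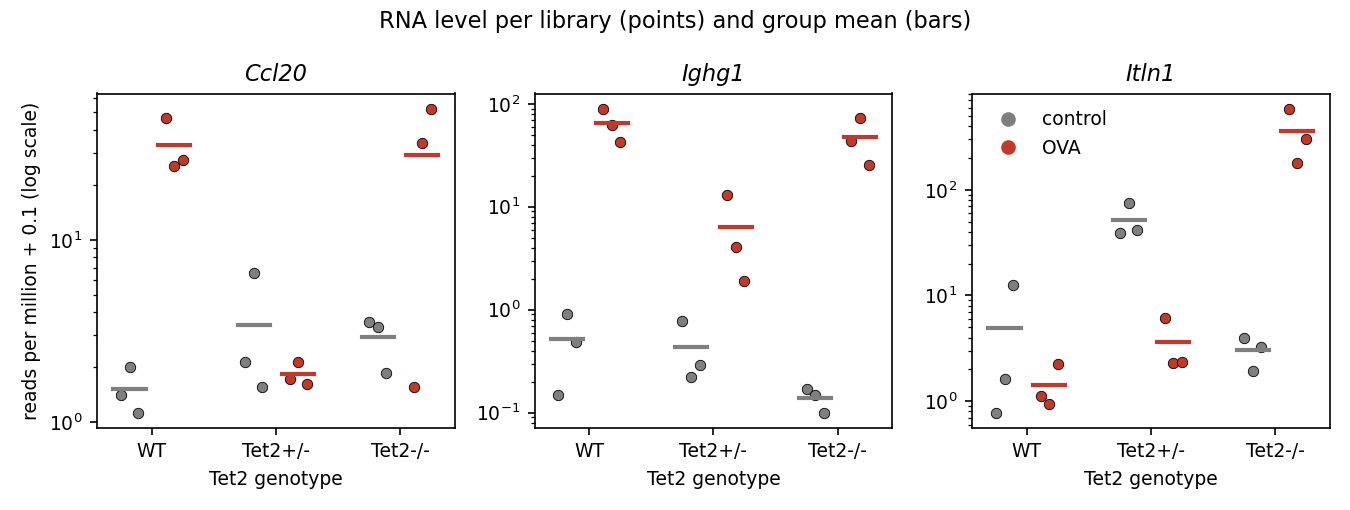
CPM plus 0.1 on a log axis for Ccl20, Ighg1 and Itln1 in each of the 18 RNA libraries by group, each point a library. Itln1 was highest in the Tet2-/- OVA libraries (180 to 585), and Ccl20 was low in 1 Tet2-/- OVA library (1.46).

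Of 28 lists tested in Tet2-/-, 16 rose and 1 fell at the preset correlation. With an estimated correlation no list passed (adjusted p = 0.554 for the lists that rose and 0.610 for olfactory neurons), so each list call below holds at the preset correlation only. Type 2 epithelial and macrophage response genes were higher in 20 of 22 members (median log2 change 1.85, camera adjusted p = 8.37e-12), with 1 called and 7 adjusted over the list alone. Chil4 was at 6.68, the mucus protein Fcgbp at 3.50 and Retnla at 3.41. Antigen presentation genes were higher in 18 of 18 members (median 1.62, 8.37e-12), 6 of them adjusted over the list alone, with Cd74 at 1.96, H2-Ab1 at 1.86 and Tapbp at 0.77. Plasma cell genes rose (15 of 16 higher, 8.94e-10, 4 adjusted over the list alone), with Igkc at 3.29 and Mzb1 at 1.77. Interferon-stimulated genes tested as higher (26 of 26 higher in sign, median 1.24, 2.10e-09), with Gbp2 at 2.81, Zbp1 at 2.59 and Oas3 at 2.25. NF-kB targets were higher in 21 of 21 (median 1.09, 1.90e-06), with Il1rn at 3.00 and Il1b at 1.24, and T cell markers in 13 of 13 (median 1.53, 8.81e-06), with Trac at 1.98 and Lck at 1.44. Basal and secretory epithelium (15 of 16 higher, 0.000147), macrophage (17 of 18, 0.000202), tight junction (15 of 17, 0.00229), ciliated (16 of 20, 0.00629), cartilage (16 of 20, 0.0115), nasal gland (14 of 19, 0.0126) and erythroid lists (5 of 5, 0.0483) also rose. With the replicate number as a block the erythroid list did not pass (0.0841), and cytotoxic lymphocyte markers did (0.0383). Of all lists from interferon-stimulated genes on, the nasal gland list had 1 member adjusted over the list alone and the others 0. Neutrophil markers tested as higher (0.0362) with a mean of 0.70 but a median of −0.14, 7 of 15 members higher and 2 rises adjusted over the list alone; Lcn2 was at 4.00. Olfactory neuron markers fell (21 of 22 lower, median −0.39, 0.00527), with Gap43 at −0.99. Keratinocyte markers (18 of 18 higher, median 3.73, 5.43e-09) and skeletal muscle markers (17 of 18, median 3.58, 2.02e-08), which belong to other tissues, moved with these lists. Keratinocyte genes summed to 865, 974 and 1653 CPM in Tet2-/- OVA and to 45.3, 79.0 and 1207 in Tet2-/- control libraries, and muscle genes to 619, 502 and 658 against 18.2, 16.5 and 552. With a covariate for these markers 5 of the 17 lists passed (type 2 epithelial, plasma cell, neutrophil, antigen presentation and interferon-stimulated genes), and glia markers and mitochondrial transcripts newly passed as lower. With the Bpifb9a and Bpifb9b covariate 14 of the 17 passed, and the neutrophil (0.227), cartilage (0.227) and erythroid lists (0.158) did not. Type 2 cytokines (0.104), B cell (0.0818) and cytotoxic lymphocyte markers (0.193 without the block) did not pass. The calls of Itln1 and Ighg1 were lost in edgeR (0.0560 and 0.0636), with the keratinocyte and muscle covariate (0.0536 for both) and without Tet2-/- OVA replicate 1 (0.0804 for both) or 3 (0.0537) and Tet2-/- control replicate 1 (0.0757) or 2 (0.0834 and 0.117), and that of Ighg1 also without OVA replicate 2 (0.0652) and with the covariate for Bpifb9a and Bpifb9b (0.0918). Without control replicate 3, which had Xist reads and the high keratinocyte and muscle level, 83 genes were called. Over 20 alternatives the adjusted p ranged from 1.86e-64 to 0.0834 for Itln1 and from 1.39e-16 to 0.117 for Ighg1.

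**Figure D2:**
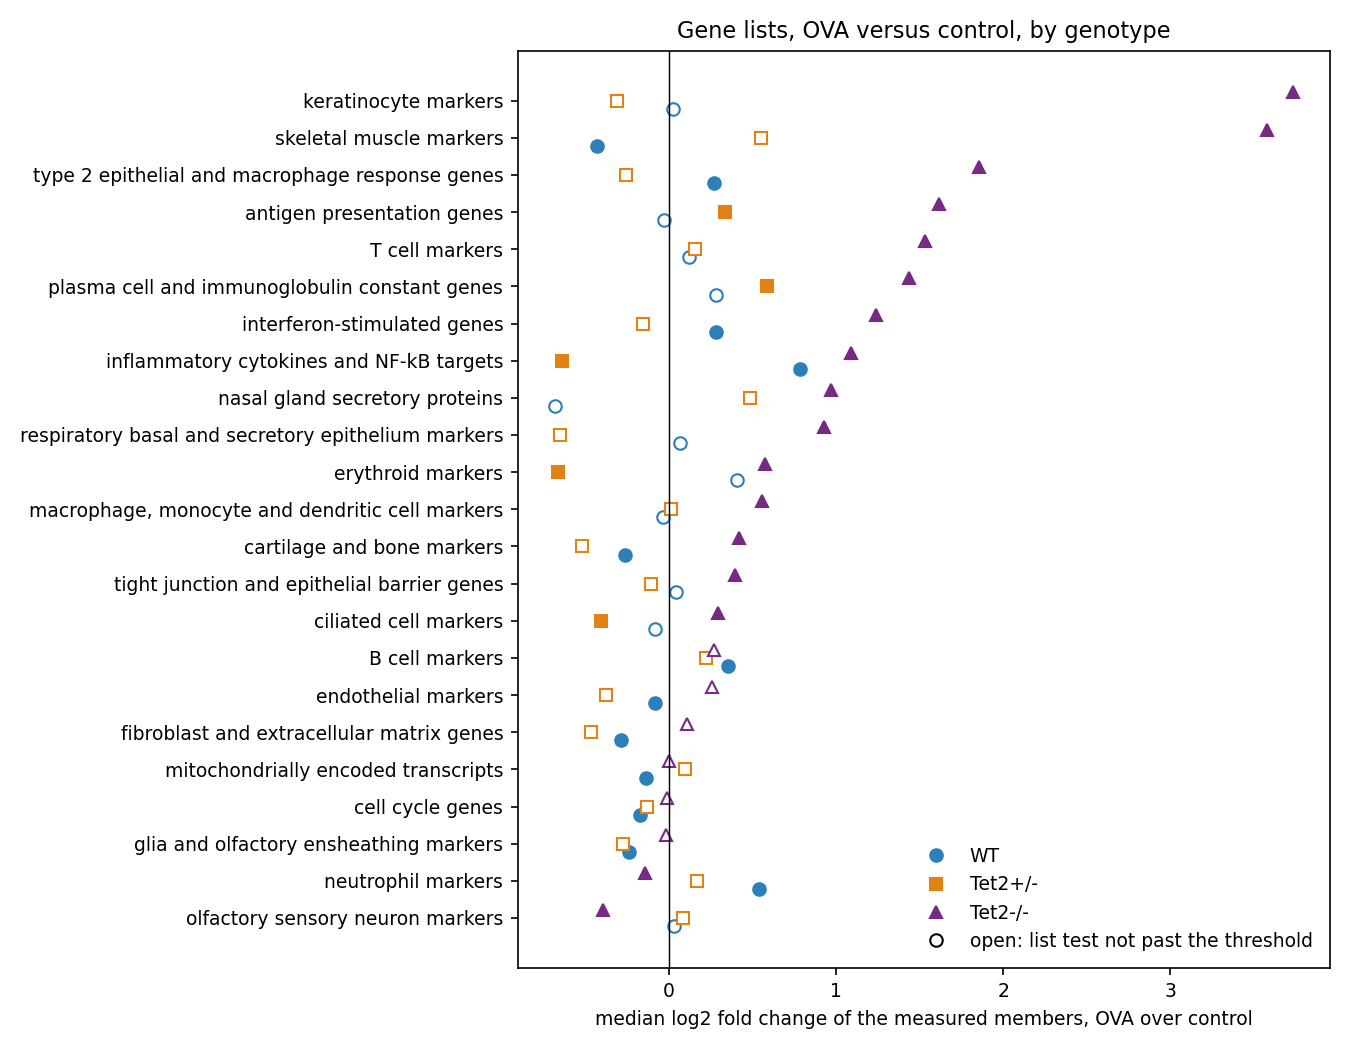
Median log2 change of each gene list with OVA in each genotype, on a common axis, filled where the list passed camera's threshold at the preset correlation. Keratinocyte (3.73) and muscle (3.58) lists had the highest medians in Tet2-/-.

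Whether the OVA effect depended on Tet2 was asked as a difference of effects. That of Itln1 was 7.96 ± 1.09 (log2 ± SE) higher in Tet2-/- than in WT (limma adjusted p = 0.0315) and 10.41 ± 1.09 higher than in Tet2+/- (0.00118). Itln1 was at 1.33 ± 0.69 and 4.86 ± 6.53 CPM in WT OVA and control libraries, and in Tet2+/- it was lower with OVA (3.50 ± 2.19) than without (51.7 ± 20.0, SD, n = 3). Gm9765 followed at 5.90 and 7.86, and in Tet2+/- it had 0 OVA and 13 control reads, 3.42-fold lower against the floor (lower limit 2.41 by counting). These were the 2 genes called in each of these contrasts, with 984 and 1692 of 19978 at an unadjusted p under 0.05, and DESeq2 called 10 and 46. The 984 for Tet2-/- minus WT did not exceed the share of 0.05 that chance gives. With the replicate number as a block, 1 gene was called against WT, where Gm9765 lost its call, and 526 against Tet2+/- (438 higher, 88 lower). The numbers were not taken to pair OVA and control libraries of WT or Tet2+/-. For Tet2+/- such pairing stays open, since the pairing taken for the other mutant comparisons would also link its libraries. For Tet2+/- minus WT limma called 0 genes, with 1630 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 182. Ccl20 differed by −4.55 there (0.394) and Scgb2b2 by 5.66 (0.144). Ighg1 was not shown to differ between Tet2-/- and Tet2+/- (4.68, 0.412). The Itln1 difference from Tet2+/- stayed called under all 20 alternatives (adjusted p of at most 0.0136). That from WT was lost with a mean of at least 50 (0.0548), in a fit of only the 12 libraries (0.371) and without the libraries with Xist reads (0.184), at differences of 6.79 to 8.95 over 20 alternatives. It was also lost without each Tet2-/- or WT OVA library, each Tet2-/- control library or WT control replicate 2, up to 0.264 without Tet2-/- OVA replicate 3, and stayed without WT control replicate 1 or 3.

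Of 27 lists, 16 differed between Tet2-/- and WT in their OVA effect, 6 between Tet2+/- and WT and 16 between Tet2-/- and Tet2+/- at the preset correlation. None passed with an estimated correlation, where the adjusted p lay between 0.586 and 0.711, 0.916 and 0.985, and 0.0861 and 0.619 in this order. Against Tet2+/-, the effect on type 2 epithelial genes was higher in Tet2-/- for 20 of 20 members (median difference 2.29, camera adjusted p = 4.16e-09, 1 called and 7 adjusted over the list alone), and this list was closest to the threshold with an estimated correlation (adjusted p = 0.0861) and passed fry (0.00905). NF-kB targets (21 of 21, median 1.84), interferon-stimulated genes (26 of 26, 1.36), antigen presentation (18 of 18, 1.25), ciliated markers (20 of 20, 0.72) and basal and secretory epithelium (15 of 16, 1.43) were higher in the same contrast, and olfactory neuron markers lower (21 of 22, −0.52). Against WT, antigen presentation (18 of 18, median 1.58, 2.80e-13, 6 adjusted over the list alone), plasma cell (16 of 16, 1.40, 6.80e-06) and nasal gland genes (15 of 19, 2.14, 0.000853) were higher in Tet2-/-. Keratinocyte and muscle markers were higher in both contrasts, with medians of 4.00 and 4.19 against WT and 3.62 and 2.80 against Tet2+/-. For Tet2+/- minus WT, NF-kB targets were lower in 21 of 21 members (median −1.74, 1.83e-08) and type 2 epithelial genes in 18 of 20 (−1.02, 0.0212). Ciliated markers were lower in 19 of 20 (−0.39, 0.00503), erythroid markers in 6 of 7 (−1.01, 0.00862) and basal and secretory epithelium in 13 of 16 (−0.55, 0.0478). Mitochondrial transcripts were higher in 10 of 13 (0.23, 0.0212). Within Tet2+/-, the NF-kB and ciliated lists had turned to higher with the Bpifb9a and Bpifb9b covariate, which was not fitted for differences of effects.

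Tet2-/- and Tet2+/- libraries were compared within each treatment, in the same run of libraries as far as their names show. In control mice edgeR called 1 of 19962 genes, the ribosomal pseudogene Rpl34-ps1 (3.13 ± 0.20, adjusted p = 0.0395), which was named after its value was seen and may share reads with its parent gene; 656 had an unadjusted p under 0.05, and DESeq2 called 215 (207 lower). With the pairing as a block edgeR called 9 (8 lower), and with no filter 66 (63 lower). The call of Rpl34-ps1 was lost on leaving out each of the 6 libraries, with 0 genes called each time. Itln1 was lower in Tet2-/- controls by −4.09 ± 0.40 (0.139, from 1.31e-21 to 0.486 over 11 alternatives), Calr4 was at −4.75 and S100z at −2.94, none past the threshold. In OVA mice edgeR called 0 of 19416 genes, with 608 at an unadjusted p under 0.05, against 29 by DESeq2 and 4 with the block. Neither this 608 nor the 656 of control mice exceeded the share of 0.05 that chance gives. Itln1 was at 6.26 ± 0.57 (0.502), and passed with the block (6.34, 0.0341), within a range of 2.17e-33 to 1.00 over 10 alternatives. Alox12e (3.30), Nr4a2 (−1.17) and Pim3 (−1.07) did not pass. Leaving out Tet2+/- OVA replicate 3 gave 3 calls.

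Of 28 lists, 12 were lower in Tet2-/- than in Tet2+/- controls and none higher at the preset correlation. None passed with an estimated correlation in control (adjusted p from 0.186 to 0.707 for the 12 lists) or in OVA mice (0.140 to 0.644 for 16). With the replicate number as a block 18 lists passed in control mice, and olfactory neuron markers were then higher (0.000546), while in OVA mice 17 passed and B cell markers no longer did (0.134). Interferon-stimulated genes were lower in 24 of 24 members (median −0.67) and antigen presentation genes in 18 of 18 (−0.63), both with a camera adjusted p of 5.94e-12, an estimated-correlation adjusted p = 0.410, and 0 and 3 members adjusted over the list alone. Erythroid markers were lower in 6 of 6 (−0.84, 5 adjusted over the list alone) and NF-kB targets in 17 of 18 (−0.74). Nasal gland proteins were lower in 14 of 19 (−0.57, 6 adjusted over the list alone) and type 2 epithelial genes in 17 of 20 (−0.88). Keratinocyte genes summed to 108, 629 and 1826 CPM in Tet2+/- and to 45.3, 79.0 and 1207 in Tet2-/- control libraries. In OVA mice 15 lists were higher in Tet2-/- and 1 lower. Type 2 epithelial genes were higher in 21 of 22 (median 1.25, 1.22e-11, 5 adjusted over the list alone, adjusted p = 0.237 with an estimated correlation), NF-kB targets in 18 of 19 (1.15), ciliated markers in 20 of 20 (0.42), interferon-stimulated genes in 26 of 26 (0.69) and T cell markers in 13 of 13 (0.74), and olfactory neuron markers were lower in 21 of 22 (−0.40). Keratinocyte (18 of 18, 2.83) and muscle markers (16 of 18, 2.44) were higher as well. Without Tet2+/- OVA replicate 1 the count in OVA mice was 5 and without Tet2-/- OVA replicate 3 it was 6.

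5hmC peak lists were compared to ask whether treatment moved the mark in each genotype. WT OVA libraries had 57348.5 ± 9062 peaks (SD, n = 2) and WT controls 43983 ± 7148 (n = 3), with an exact two-sided permutation p of 0.2. Tet2+/- had 86448 ± 10815 with OVA and 115446 ± 15362 without (n = 3 each, exact p = 0.1), and Tet2-/- had 135171 ± 5948 with OVA (n = 2) and 94017 ± 16359 without (n = 3, exact p = 0.2). In each genotype the OVA and control libraries did not overlap, which chance gives in 10% of 3 against 3 splits and 20% of 2 against 3, and the smallest p these designs allow is 0.1. On leaving out a library the difference ranged from 6958 to 19773 peaks in WT, −36210.5 to −20921.5 in Tet2+/- and 33432.5 to 49725 in Tet2-/-. Peaks covered 25.5 Mb with OVA and 18.0 Mb without in WT, 39.0 and 53.5 Mb in Tet2+/-, and 65.4 and 42.2 Mb in Tet2-/- (exact p = 0.1 each, 0.283 after Benjamini-Hochberg adjustment over 34 tests). Median fold enrichment moved the other way, from 4.84 to 5.32 in Tet2+/- and from 4.98 to 4.55 in Tet2-/-. The difference of OVA effects between Tet2-/- and Tet2+/-, a contrast chosen after seeing the data, was 70151 peaks (exact two-sided permutation p = 0.01 of 200 arrangements). With peaks of at least 4-fold enrichment it was 29616 and did not pass (exact permutation p = 0.07). These tests did not pair the libraries, and they treat lists of a group as independent although these may share an input library. Paired by replicate number, all 3 differences in Tet2+/- were negative and both in Tet2-/- positive, with all peaks and at 4-fold enrichment, and the exact sign-flip p was 0.0625 for each, the smallest possible. Over both treatments Tet2-/- had 110479 and Tet2+/- 100947 peaks (exact p = 0.494). Tet2-/- OVA libraries had more peaks than Tet2+/- OVA libraries without overlap (exact p = 0.1).

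**Figure D3:**
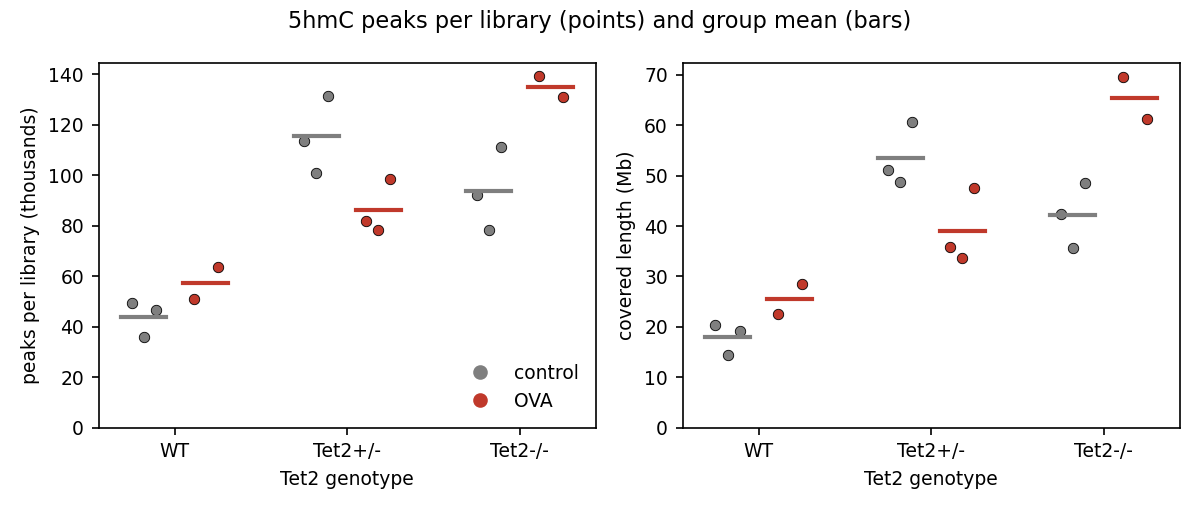
Number of peaks and covered length in Mb for each of the 16 5hmC libraries by group, each point a library. OVA libraries lay above controls in WT and Tet2-/- and below them in Tet2+/-.

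Peaks sat in genes more often than the genome as a whole. Introns held 55.4% to 60.4% of peaks per library and 37.9% of the genome, promoters 12.5% to 14.0% against 5.47%, exons 8.69% to 10.8% against 3.04%, and intergenic sequence 17.1% to 21.5% against 53.6%. Tet2-/- libraries had a lower exon share than Tet2+/- libraries (9.30% and 10.4%, n = 5 and 6, exact p = 0.0130) and a higher intron share (58.4% and 56.4%, exact p = 0.0476), both 0.283 after adjustment over 34 tests. Libraries of a group shared more peak bases with each other than with the other treatment in Tet2+/- (Jaccard difference 0.0645, exact one-sided p = 0.1) and Tet2-/- (0.0632, 0.1), and not in WT (−0.0111, 0.7); 0.1 is the smallest p possible. The WT sign turned without any of the 3 control libraries (0.0106, 0.000893 and 0.00518). Tet2-/- and Tet2+/- libraries differed in the same measure (0.0257, exact one-sided p = 0.0130), also with the same number of peaks per library (0.0295, 0.00216, the smallest possible). That measure counts pairs within a treatment group as pairs of a genotype. Pairs of a genotype across treatments (mean Jaccard 0.340 in Tet2+/- and 0.334 in Tet2-/-) were no more alike than pairs across genotypes (0.312 to 0.367), so the difference is not attributed to genotype.

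Regions with a peak in every OVA and no control library numbered 3969 in WT, 1321 in Tet2+/- and 17571 in Tet2-/-, and the reverse 555, 7116 and 2015. They came from 114926, 202017 and 214172 merged regions, of which 9997, 30116 and 35720 were in every library of the genotype. With the same number of peaks per library the regions of OVA libraries only numbered 1915, 1546 and 3361 and the reverse 886, 1698 and 2055, so these counts moved with the length of the lists. Other splits of the libraries gave at most 4353 regions in WT against 4524, 3025 in Tet2+/- against 8437 and 9157 in Tet2-/- against 19586.

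At Tslp, an epithelial alarmin of type 2 responses (chromosome 18, 32815383 to 32819797), a peak lay upstream of the gene in 3 of 3 control and no OVA library of Tet2+/- (32813810 to 32814174) and likewise of Tet2-/- (32813726 to 32814124), and in no WT library. Tslp RNA was low, at 0.32 ± 0.26 and 0.54 ± 0.29 CPM in Tet2+/- OVA and control libraries (SD, n = 3). At Il33, another alarmin, 2 regions within the gene had a peak in both WT OVA and no WT control library (chromosome 19, 29940556 to 29940879 and 29944424 to 29945295). Tet2 itself carried peaks in all 16 libraries, with 1 region of OVA libraries only in WT (133487589 to 133488331), 1 of controls only in Tet2+/- (133533071 to 133533579) and 1 of OVA only in Tet2-/- (133521970 to 133522693). Tet1, a gene of 104 kb, had 6 regions of OVA libraries only in Tet2-/-. Over all genes compared, 29.8% had such a region in Tet2-/- and 11.4% in WT. Regions of controls only were at 17.1% of genes in Tet2+/- and 5.81% in Tet2-/-. Of 19 TET, DNMT and related genes, 7 had a Tet2-/- region of OVA libraries only, against 6.86 in matched random lists. Gata3 had a peak in 1 of 2 WT OVA and 2 of 3 Tet2-/- control libraries, Il4 in 2 of 2 Tet2-/- OVA and 1 of 3 Tet2-/- control, 1 of 3 Tet2+/- OVA and 2 of 3 Tet2+/- control, and 1 of 3 WT control libraries, and Il13 in 1 of 3 Tet2+/- OVA, 2 of 3 Tet2+/- control and 1 of 3 Tet2-/- control libraries. Itln1 had a peak in 1 of the 16 libraries, a Tet2+/- OVA library, and Ighg1, Ccl20, Cabs1, Odam, Scgb2b2 and Il5 in none, whereas Derl3 had one in 15 of 16 and Bpifb5 in 10 of 16.

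Genes whose RNA rose were compared with other genes for carrying a peak, across genes, which are not independent replicates. A peak lay at 0 of 2 called genes in WT (Fisher's exact p = 0.50005), 2 of 13 in Tet2+/- (0.000162) and 0 of 3 in Tet2-/- (0.0343), while 50.6%, 32.5% and 32.5% of all genes had none. With the same number of peaks per library the p was 0.0233 in Tet2+/- and 0.256 in Tet2-/-. The test did not match genes by length. The called genes named by the rule were 2.11 kb (Cabs1) to 17.8 kb (Pnliprp2) long. A low share with peaks may follow gene length and is not read as a trait of genes that rose. Between the 28 lists and the regions of a group, 168 tests gave a lowest permutation p of 0.00160, for macrophage markers with 0 of 18 members at Tet2-/- OVA regions against 5.00 in matched random lists, which is 0.269 after Benjamini-Hochberg adjustment.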

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

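The covariates were chosen after the data were seen, but for the list tests with them the bounds were set before those tests were run, when gene results with the same covariates had been seen; every other test of an explanation in this part, and the contrast of peak numbers, was chosen only after the result was seen. The counts of genes and lists are set beside other splits of the same libraries. These splits and the counts beside them did not use the pairing by replicate number.

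The OVA effect on 5hmC peak number differed between Tet2-/- and Tet2+/- by 70151 peaks and by 37.7 Mb of covered length (exact two-sided permutation p = 0.01 and 0.005 of 200 arrangements). Another sex of 1 control mouse of each mutant genotype, seen as Xist reads, is a possible source, but without these mice the difference was 70646.5 (exact permutation p = 0.0333 of 60), which argues against it. Sequencing depth stays open and cannot be told apart from treatment. The same holds for the input library, if each mutant group was called against its own input. The caller background may follow depth, which was not checked, and in WT it was 1.675 to 1.767 for lists of 35918 to 63756 peaks. Its OVA effect differed between Tet2-/- and Tet2+/- by 1.75 under the last of 4 rules tried (permutation p = 0.005). It differed by −1.43 under the most frequent solution (permutation p = 0.355). The sign turned through libraries with a solution of 0 (Tet2-/- OVA replicate 1), 0.001 (Tet2+/- control replicate 1) or 3.85 (Tet2-/- control replicate 3). Where both rules gave the same value, the background was 1.65 to 1.76 with OVA and 2.35 and 2.45 without in Tet2+/-. In Tet2-/- it was 2.785 with OVA and 2.115 and 2.149 without. These directions are those of the peak numbers. An OVA effect that depends on Tet2 genotype may also account for the difference in peak number, and stays open. At peaks of at least 4-fold enrichment the difference had an exact permutation p of 0.07 unpaired. Paired by replicate number, the exact sign-flip p was 0.0625, the smallest possible, and each genotype kept a single sign.

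Itln1 rose with OVA in Tet2-/-, and its effect differed from WT by 7.96 and from Tet2+/- by 10.41 (log2), as did the neighbouring pseudogene Gm9765 by 5.90 and 7.86. A single library may be the cause, but the lowest difference from WT on leaving out a library was 6.79 ± 0.74 (SE, 1.09 with all libraries). This argues against it as the whole cause, although most other omissions ended the call, at 7.65 to 8.35 with an SE of 1.16 to 1.20. The gland share may be a cause, but with the Bpifb9a and Bpifb9b level as a covariate the Tet2-/- change was 7.33 ± 0.35 (7.01 ± 0.37 without). This argues against the gland share as the whole cause of the rise in Tet2-/-. The covariate was not fitted for the differences between genotypes. In Tet2+/- the gland share was higher with OVA and Itln1 lower, so a part of the difference from Tet2+/- stays open to it. Keratinocyte and muscle tissue is argued against as the whole cause of the rise in Tet2-/- by a change of 6.68 ± 0.52 with its covariate against 7.01 ± 0.37 without. The call ended (limma adjusted p = 0.0536 against 0.00902) as the spread grew and the change fell slightly, and a part of the change stays open to such tissue. The differences between genotypes were not fitted with its covariate either. Another sex of 2 control mice is argued against by a difference of 8.14 ± 1.23 without those libraries, against 7.96 ± 1.09 with them, where the call against WT was lost (adjusted p = 0.184) as the spread grew. A genotype-dependent response is left as a hypothesis that no separate libraries tested. Beside it stay a part due to the gland share or to keratinocyte and muscle tissue, and shared reads between Itln1 and its relatives, which were not tested. Chance also stays, since 14 and 6 of 100 splits, the real grouping included, reached the counts of 2 genes.

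In Tet2-/- 17 lists moved together with OVA, and the OVA effect on lists differed from WT in 16, from Tet2+/- in 16, and between Tet2+/- and WT in 6, all at the preset correlation only, since with an estimated one 0 passed (lowest adjusted p 0.554, 0.586, 0.0861 and 0.916). Tissue of another kind in the sample, with keratinocytes and muscle, could move many lists at once. With the keratinocyte and muscle level as a covariate 7 lists passed, 5 of them among the 17, in line with such a contribution, although this level had a correlation of 0.697 with OVA, so a part of the treatment effect is removed with it. Whether such tissue also accounts for the 5 that stayed is open. With the gland share as a covariate 15 lists passed, 14 of them among the 17. By the bound set, this goes against that share as the whole cause. Since other splits of these libraries gave up to 19 lists, neither covariate's count decides the cause.

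Among the 6 Tet2+/- 5hmC libraries, the share of peaks on the X chromosome stood apart in control replicate 3 at 0.569%, the replicate number whose RNA had Xist reads. It was the 1 of 18 such tests beyond its limit, where chance gives about 1 in 20.

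In each 3 against 3 comparison the 10 splits, which include the real grouping, are too few for a share under 0.05. Each number of splits that reached a count includes the real grouping, so 1 split means that no other split reached it. WT gave 2 genes and 12 lists against at most 267 and 18 in other splits, which 3 splits reached in each case, and a split that calls 267 genes points to a structure of the WT libraries other than treatment. Tet2+/- gave 13 genes, reached by 1 split, against at most 2, and 5 lists, reached by 9 splits, against at most 17. Tet2-/- gave 3 genes, reached by 1 split, against 0, and 17 lists, reached by 3 splits, against at most 19. Tet2-/- against Tet2+/- gave 1 gene in control mice, reached by 2 splits, with 11 the highest other, and 0 in OVA mice, with 0 the highest other over 10 splits. The 12 and 16 lists of these contrasts were each reached by 5 splits, with at most 15 and 21. The 8437 5hmC regions of a single group in Tet2+/- were reached by 1 split, against at most 3025.

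For the differences of OVA effects 100 splits were taken, with the real grouping among them and counted in the same way. The 2 genes for Tet2-/- minus WT were reached by 14 splits (highest other 19), the 0 for Tet2+/- minus WT by 100 (highest other 4) and the 2 for Tet2-/- minus Tet2+/- by 6 (highest other 6877), so chance is not excluded for these counts. The 16, 6 and 16 lists were reached by 24, 70 and 19 splits, with at most 20, 19 and 20. The split with 6877 genes points to a structure of the mutant libraries that the groups do not capture.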

How the results depend on the processing

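The covariates, the fits without the libraries with Xist reads, the authors' deposited table and the settings for the difference of peak numbers were chosen only after the results were seen. Of the values of named genes under other settings 3132 kept direction and side of the threshold, 195 passed newly, 28 no longer passed and 20 reversed. On leaving out a library these were 3000, 9, 43 and 15. Most named genes were not called in the main fit and count as kept where they stayed uncalled. The 28 and 43 came only from the few genes called in the main fit, so the large counts do not show that calls were stable. Of counts and measures 93 of the other settings stayed within their limits, 81 moved and 3 weakened. Where no cause is given, the cause was not tested.

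The WT count of 2 genes became 7 with a pseudocount of 5, 6 with no filter, 4 with a mean of at least 50, 4 with median centring, 1 with robust moderation, 1 with all 18 libraries, 0 with the Bpifb9a and Bpifb9b covariate, 1 with the keratinocyte and muscle covariate, 92 in the authors' deposited table and 93 with DESeq2. The Tet2+/- count of 13 became 6, where fewer genes were tested, with a mean of at least 50, 403 with all 18 libraries, 0 and 24 with the covariates, 692 in the authors' deposited table, 6 with edgeR and TMM and 838 with DESeq2. The Tet2-/- count of 3 became 0 with edgeR under size factors or TMM, 5 with all 18 libraries, 1 with either covariate, 130 in the authors' deposited table and 102 with DESeq2. For Tet2-/- minus WT the 2 became 0 with a mean of at least 50, 1 with 12 libraries, 1 without the Xist libraries, 1 with edgeR and 10 with DESeq2. For Tet2+/- minus WT the 0 became 1 with no filter, 35 with 12 libraries, 5 without the Xist libraries and 182 with DESeq2. For Tet2-/- minus Tet2+/- the 2 became 1 with a mean of at least 50, 5 without the Xist libraries, 1 with edgeR and 46 with DESeq2. Tet2-/- against Tet2+/- gave 215 in control and 29 in OVA mice with DESeq2, 66 and 1 with no filter and 0 in controls without the Xist libraries. DESeq2 also made more false calls in simulation.

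With the replicate number as a block the counts were 5 in WT, 415 in Tet2+/-, 17 in Tet2-/-, 1, 81 and 526 for the differences in the order above, and 9 and 4 for Tet2-/- against Tet2+/- in control and OVA mice; 10 lists passed for Tet2+/- minus WT. In WT and Tet2+/- the numbers were not taken to pair OVA and control libraries, and not every library correlated best with its own number. Same-number correlations were 0.29, 0.06 and −0.07 in WT, and 0.29, 0.10 and 0.62 in Tet2+/-. For Tet2+/- pairing stays open, since the pairing taken for the other mutant comparisons would also link these libraries. Olfactory neuron markers fell from replicate 1 to 3 in Tet2+/- OVA (9960, 6158 and 3541 CPM) and control libraries (11259, 9172 and 4892). The same order held in both Tet2-/- groups. Itln1 kept its call in Tet2-/- minus WT with the block, where Gm9765 lost it. In the paired comparisons Fcgbp, Lcn2, Bpifb1 and Pigr passed newly in Tet2-/-, Fcgbp in control mice and Itln1 and Alox12e in OVA mice, where Pvalb changed sign (1.46). Lcn2 and Slc6a14 in WT, and further named genes in Tet2+/- and in the differences from it, also passed newly. Lists changed in all 8 comparisons, for example in WT, where B cell (0.107) and endothelial (0.0572) lists no longer passed and plasma cell (0.0448) and erythroid lists (0.0490) did.

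With an estimated correlation 0 lists passed in each of the 8 comparisons, and with fry 0 except 1 for Tet2-/- minus Tet2+/- and 2 for Tet2-/- against Tet2+/- in controls. Tet2+/- had 8 lists with the Bpifb9a and Bpifb9b covariate and Tet2-/- 7 with the keratinocyte and muscle covariate.

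Leaving out each library gave 1 to 6 genes in WT, 1 to 12 in Tet2+/-, 0 to 83 in Tet2-/-, 0 to 2, 0 to 9 and 1 to 3 for the differences, 0 to 0 in control and 0 to 3 in OVA mice. Lists ranged from 4 to 12 in Tet2+/-, 11 to 20 in Tet2-/-, 3 to 9 for Tet2+/- minus WT and 5 to 21 for Tet2-/- against Tet2+/- in OVA mice. The promoter share difference between Tet2-/- and Tet2+/- ranged from −0.636 to −0.320 points, and passed without Tet2-/- control replicate 3. The WT Jaccard difference ranged from −0.0372 to 0.0106.

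Regions of OVA libraries only became 2507 in WT with −log10 q of at least 5 and 1915 with the same number of peaks, 2214 in Tet2+/- with 50% reciprocal overlap and 6481 with at least 2 libraries, and 3361 in Tet2-/- with the same number. Regions of control libraries only became 341, 886 and 4670 in WT with −log10 q of at least 5, the same number and at least 2 libraries, 1698 and 23250 in Tet2+/- with the same number and at least 2 libraries, and 3765 and 9471 in Tet2-/- with reciprocal overlap and at least 2 libraries. The difference of peak numbers was 29616 (exact permutation p = 0.07) at 4-fold enrichment, and paired by replicate number 78722.7 with all peaks and 36001.8 at 4-fold enrichment (exact sign-flip p = 0.0625 each, the smallest possible).

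Signs reversed with the Bpifb9a and Bpifb9b covariate for Tet1 (0.0631), Tet3 (0.15) and Des (0.33) in WT and for Nlrp3 (0.79), Sele (0.26), Dnah9 (0.58), Rsph4a (0.47), Cfap43 (0.69) and Hba-a2 (0.15) in Tet2+/-. With the keratinocyte and muscle covariate they reversed for Tet3 (0.0603) and Tet2 (−0.0554) in Tet2-/-, and without the Xist libraries for Tet3 (−0.0186) in Tet2-/- minus Tet2+/- and Alpl (0.10) in control mice. For Tet2-/- minus Tet2+/-, Pvalb, Myh4 and Myh1 were at −0.25, −0.21 and −0.78 with edgeR and −0.27, −0.23 and −0.79 with DESeq2. On leaving out a library, Tet2 ranged from −0.0876 to 0.12 in WT, −0.0145 to 0.31 in Tet2-/-, −0.0262 to 0.30 in Tet2-/- minus WT and −0.29 to 0.0255 in control mice. Tet3 ranged from −0.12 to 0.0142 in WT and −0.11 to 0.14 in control mice, and Tet1 from −0.0925 to 0.23 in Tet2+/-, −0.68 to 0.0137 in Tet2-/-, −0.49 to 0.21 in Tet2-/- minus WT and −0.34 to 0.24 in OVA mice. In OVA mice Actn3 ranged from −2.19 to 1.15, Pvalb from −1.69 to 4.15 and Krt6a from −0.16 to 5.21. Genes below a mean of 10 were not tested, and the depth of the 5hmC libraries is unknown.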

Other observations

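The lists of eosinophil and adipocyte markers had too few members above the level for a test. Eosinophil markers summed to 35.9, 32.6 and 35.0 CPM in WT OVA and 33.1, 33.5 and 29.4 in WT control libraries, and to 20.6, 14.2 and 9.62 in Tet2-/- OVA against 18.4, 14.3 and 11.7 in Tet2-/- control libraries. Adipocyte markers ranged from 6.15 to 45.7 CPM, with the highest level in Tet2+/- OVA replicate 3. The transcripts of the type 2 cytokines Il5 and Il13 stood at or below 0.81 CPM in every library.

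Xist, expressed from the inactive X chromosome of females, stood at 547 CPM in Tet2+/- control replicate 3 and 738 in Tet2-/- control replicate 3, and at 0.99 or less in the other 16 RNA libraries. The 5hmC libraries with the same replicate numbers had the most X-chromosome peaks, 749 and 661, against 168 to 449 in the other mutant libraries and 19 to 73 in WT. The 10 genes with most reads took 5.31% to 6.73% of reads in WT libraries and up to 42.4% in the mutant ones. Bpifb9a and Bpifb9b took 1.49%, 15.9% and 16.01% of reads in Tet2-/- OVA libraries, 1.94%, 15.3% and 0.0165% in Tet2-/- control libraries and at most 0.121% in WT. Muscle genes summed to 2152 CPM in Tet2+/- OVA replicate 3 and 592 in Tet2+/- control replicate 3, against 10.2 to 28.2 in the other Tet2+/- libraries.

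Itln1 stood apart between the mutant controls, although not past the threshold, with 38.6 to 74.7 CPM in Tet2+/- and 2.94 ± 1.03 in Tet2-/- control libraries (SD, n = 3), and WT controls held up to 12.4.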
